A study of Oryza sativa with 4 samples.

How the data were processed

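Gene expression in leaves of 2 rice (Oryza sativa) lines was compared on 4 Agilent oligonucleotide arrays with 2 colours each. NIL37, susceptible to rice stripe virus, was labelled with Cy3 on all 4 arrays, and its resistant sister line NIL22 was labelled with Cy5. Both are near-isogenic BC4 backcross lines from the recurrent parent Ilpum and the donor Shinkwang. RNA came from plants 14 days old, either healthy (2 arrays) or inoculated with rice stripe virus (RSV, 2 arrays). For inoculation, 3 small brown planthoppers carrying the virus were placed on seedlings 7 days old for 24 hours, and leaves were harvested 7 days later. Healthy plants received no treatment and no insects, so virus and insect feeding are not separated. Total RNA was extracted with Trizol and labelled with Agilent's linear amplification kit for low RNA input. The title of the array called Healthy 2 contains the word RSV as well as Healthy. Its source names and treatment entry both say healthy, and it was grouped by them.

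The deposited value table holds 1 log10 ratio per spot and array, red (NIL22) over green (NIL37) as made by the authors with Agilent Feature Extraction. For Healthy 2, the scanner file was also used. Per the file headers, version 8.1.1.1 of that software subtracted background with spatial detrending, normalized the dyes with a LOWESS smooth factor of 0.25, and put surrogates in place of signals not above background. The version used for the other 3 arrays and any normalization between arrays are not given in the sources used here. The scanner file gives the deposited intensity of each channel before and after these steps, per-spot flags, and the scanner software's deposited p-value for each log ratio. The Healthy 2 column of the value table equalled the scanner file's log ratio in all 22575 rows, with a largest difference of 0. That log ratio equalled log10 of red over green processed intensity within rounding, with a median absolute difference of 0.000438. The base and direction of the other 3 columns were taken to be the same, since the labels give the same software and dyes.

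Log10 ratios were put on the log2 scale, so that positive values mean a higher signal in NIL22. All folds are folds of probe signal. Whether the lines differ in sequence under a probe was not examined, so a lower signal need not mean less transcript. The 1080 control spots were left out, and 21495 probes with as many distinct accessions were tested with no filter on signal. The scanner file describes a probe by the name of an mRNA, often from another species, and 5565 probes only as an unknown expressed protein. None of the accessions (0 of 21495) was found in the gene table given as a reference, so no gene positions are given and a planned test of shares by chromosome was not run.

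Limma 3.58.1 in R 4.3.3 fitted the mean of each condition to each probe, with a moderated two-sided test and 2 residual degrees of freedom per probe. Its estimate of the prior degrees of freedom was 1.91. The 4 comparisons were the line ratio in healthy plants, the line ratio in inoculated plants, the difference between these ratios, and their average. P-values were adjusted by the Benjamini-Hochberg method over all probes within a comparison, with a threshold of 0.05. The 4 arrays share the estimate of spread, so the comparisons are not independent. No dyes were swapped (0 arrays with NIL22 in Cy3), so a dye effect specific to a gene stays in each line ratio and cancels only in the difference between conditions.

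In each comparison, the rule for named genes took up to 12 probes a side with the highest and lowest mean ratio among described probes past the threshold with the same sign on every array. Where fewer passed, up to 5 a side at 2-fold or more on every array were added and are said not to pass. The 23 gene lists comprise 17 functional lists and 6 lists of cell type markers, matched by words in the probe descriptions. They were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the lists. With an estimated correlation, camera rests on the 2 residual degrees of freedom, so it could hardly call a list. Word matching brought in some members outside a list's theme. Among these are ubiquitin and ribosomal polyproteins in the transposon list, a transposase-like clone Osh71 in the shoot meristem list and SGR2, named for shoot gravitropism, in the senescing leaf list. Comparisons, lists, the naming rule and most alternatives were fixed before the data were examined.

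Where the signal of a line was not well above background on Healthy 2, a fold is given as a lower bound. It is the other line's signal over the lowest signal that counted as well above background, which was 90.8 for NIL37 and 73.8 for NIL22. No fold is given for probes saturated in both channels or dim in both lines. Background and saturation flags are known for Healthy 2 alone. Alternatives covered centring, scaling, quantile and loess normalization, normexp background correction with an offset of 50 for Healthy 2, filters on dim or flagged spots, other variance models, a replicate block, leaving out each array, and other rules for a call. Removal of trends over the slide and intensity, and leaving out saturated probes in the list tests, were added later.

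The procedure was tested on simulated data with 21495 probes and 50 changed probes at each of 4 sizes of change. For the average of both conditions it recovered 62% of 2-fold, 90% of 4-fold and 96% of 8-fold changes. For the difference between conditions it recovered 0% of 2-fold, 36% of 4-fold and 78% of 8-fold changes. A list shifted by 0.2 was recovered in all 4 comparisons with 0 other lists called. The simulated noise was independent between probes and between arrays, so these results can overstate recovery in the data. In healthy leaves, 3 probes were 8-fold or more higher and 37 lower on both arrays, and 23 probes passed in all. Figures were drawn with matplotlib 3.10.9.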

Results

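The data set held 4 arrays, each comparing the resistant line NIL22 with the susceptible line NIL37 in the same condition, with 2 arrays for healthy and 2 for inoculated plants. The median log2 ratio of NIL22 over NIL37 lay between 0 and 0.01 on the 4 arrays. Its standard deviation over 21495 probes was 0.46 on Healthy 1, 0.40 on Healthy 2, 0.44 on RSV 1 and 0.44 on RSV 2. Probes at 2-fold or more were 239 higher and 456 lower on Healthy 1, 128 and 327 on Healthy 2, 122 and 658 on RSV 1, and 407 and 329 on RSV 2. On Healthy 2, the array with spot flags, 18990 probes were well above background in both lines, and the median signal was 957 for NIL37 and 933 for NIL22. Saturation affected 62 probes in NIL22, of which 16 were saturated in NIL37 too. The number of arrays limits the precision. The labels do not say whether repeated arrays came from separate plants, so each p measures the spread between these arrays alone.

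The first comparison asked which transcripts differ between the lines in healthy leaves. Here 23 probes passed the threshold, and all 23 had a lower signal in NIL22. A cytochrome P450-like transcript (AK099925), from a family of haem-containing oxygenases, was lower in NIL22, with a log2 ratio of -4.70 ± 0.26 (SD, n = 2, adjusted p = 0.0217). The SGR2 transcript (AK100611), whose Arabidopsis namesake is needed for shoot gravitropism, was 17.4-fold lower, at -4.12 ± 0.09 (SD, n = 2, adjusted p = 0.0199). The probe for OsPAE1 (AK103487), the alpha 5 subunit of the 20S core of the proteasome, had a 13.6-fold lower signal, at -3.77 ± 0.31 (SD, n = 2, adjusted p = 0.0269). For an alpha/beta hydrolase (AK111804), the NIL22 signal was not well above background on Healthy 2 and was at least 58.4-fold lower there.

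Of the other named probes in healthy leaves, AK100970 was at least 23.0-fold lower and AK101587 at least 19.1-fold lower on Healthy 2. The remaining ones, AK065623, AK073343, AK065423, AK067699, AK068483 and AK065550, are described by mRNAs with no named function and had mean log2 ratios from -5.27 to -2.69. With limma, 0 probes passed as higher in NIL22, and 2131 probes in either direction had an unadjusted p under 0.05. Of the named higher probes that did not pass, the receptor kinase AK099784 (adjusted p = 0.0619) and AK101732 (adjusted p = 0.249) had NIL37 not well above background on Healthy 2. They were at least 41.2-fold and at least 31.8-fold higher there, and had log2 ratios of 4.52 and 3.09 on Healthy 1. The others were the phospholipid transfer protein AK062529 (2.93, adjusted p = 0.0626), the lipid transfer protein AK063196 (2.57, adjusted p = 0.0619) and AK071988 (2.44, adjusted p = 0.354). Leaving out any of the 4 arrays left 0 probes past the threshold (880 to 2523 at unadjusted p under 0.05 with limma), and 6 passed with Healthy 2 recomputed by normexp and loess. With each array centred on its median, 41 passed, of which 5 were higher.

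The second comparison asked the same in inoculated leaves. Here 14 probes passed, and all 14 had a lower signal in NIL22. SGR2 (AK100611) was 26.3-fold lower, with a log2 ratio of -4.72 ± 0.09 (SD, n = 2, adjusted p = 0.0149). OsPAE1 (AK103487) was 12.2-fold lower, at -3.60 ± 0.02 (SD, n = 2, adjusted p = 0.0394). The cytochrome P450-like transcript (AK099925) was 11.0-fold lower, at -3.45 ± 0.14 (SD, n = 2, adjusted p = 0.0394). The named probes AK111804, AK100970, AK101587, AK065623, AK067699 and AK065550 also passed. The first 3 of them were dim in NIL22 on Healthy 2, and the last 3 had mean log2 ratios from -4.92 to -2.77.

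With limma, 0 probes passed as higher in inoculated NIL22 leaves, and 1798 in either direction had an unadjusted p under 0.05. The named higher probes were the same 5 as in healthy leaves, AK099784, AK101732, AK071988, AK063196 and AK062529, with adjusted p from 0.0718 to 0.346. All 14 probes that passed in inoculated leaves were among the 23 of healthy leaves, in the same direction. The comparisons share their estimate of spread and the dye orientation, so this overlap is not independent evidence. Leaving out any of the 4 arrays left 0 probes past the threshold (1205 to 2794 at unadjusted p under 0.05 with limma), and 5 passed with Healthy 2 recomputed by normexp and loess. With quantile normalization 26 passed, of which 4 were higher. With a replicate block 0 passed (1655 at unadjusted p under 0.05 with limma).

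The third comparison asked whether the line ratio differs between inoculated and healthy plants. No probe passed (0 with limma, smallest adjusted p = 1), and 407 had an unadjusted p under 0.05, where chance would give 1075. A count so far below chance can arise where arrays of a condition differ more than the conditions do. The RSV arrays correlated at 0.316 with each other and at 0.463 or more with the Healthy arrays. The lack of calls therefore does not show that both lines respond alike. A ratio shift of 2-fold or more between every RSV and every Healthy array was seen for 11 probes, 7 towards higher and 4 towards lower NIL22 signal. The largest described one towards higher was the expansin Os-EXP4 (AK058811), of a family that loosens cell walls. Its log2 ratio was 0.23 ± 0.26 in healthy and 1.60 ± 0.08 in inoculated leaves (SD, n = 2 each), a difference of 1.36 ± 0.18 (SE, adjusted p = 1). Towards lower, a disease resistance protein (AK072103, adjusted p = 1) and a receptor-like kinase RLK4 (AK109699, adjusted p = 1) were near background in both lines on Healthy 2, and no fold is given.

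**Figure D1:**
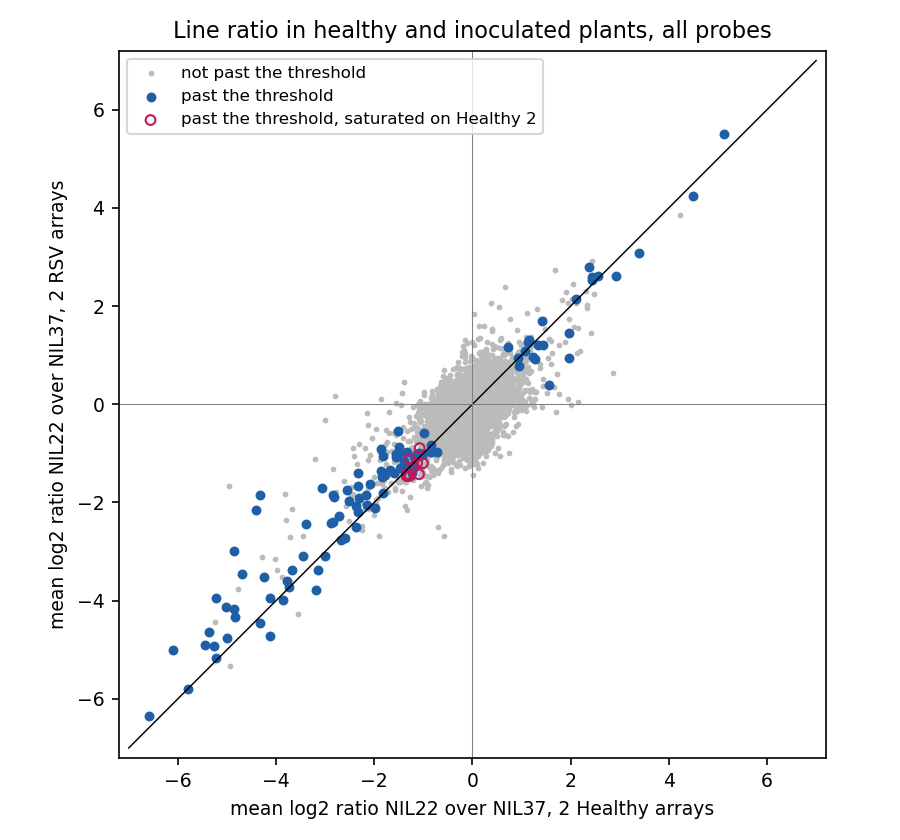
Mean log2 ratio of NIL22 over NIL37 on the 2 Healthy arrays (horizontal) against the 2 RSV arrays (vertical) for all probes, with probes past the threshold on average in blue, or as open circles where saturated on Healthy 2. The 122 probes past the threshold had the same direction in both conditions, which selection on the average largely fixed in advance.

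The fourth comparison averaged the line ratio over both conditions. Here 122 probes passed, 23 higher and 99 lower in NIL22. Among higher transcripts, a phospholipid transfer protein (AK062529) was 6.81-fold higher, at 2.77 ± 0.34 (SD, n = 4, adjusted p = 0.0241), and a lipid transfer protein (AK063196) was 6.03-fold higher, at 2.59 ± 0.23 (SD, n = 4, adjusted p = 0.0185). Such proteins carry lipids and are abundant in epidermis. The receptor kinase AK099784, not well above background in NIL37 on Healthy 2, passed as higher (adjusted p = 0.0181). It was at least 41.2-fold higher on Healthy 2, and its log2 ratios on the other arrays lay between 4.52 and 5.58. The glutathione S-transferase OsGSTU12 (AK108376), of a family that couples glutathione to reactive compounds, was 2.50-fold higher, at 1.32 ± 0.18 (SD, n = 4, adjusted p = 0.0328).

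Smaller higher ratios were those of the cellulose synthase CesA-8 (AK100914, 1.93-fold) and a beta-tubulin (AK069237, 1.91-fold), which serve wall synthesis and microtubules. The other named higher probes, AK068675, AK103457, AK103523, AK059904 and AK102279, had mean log2 ratios from 1.09 to 2.48, and the receptor kinase AK105471 was at least 1.07-fold higher on Healthy 2. Among lower transcripts, SGR2 (AK100611) was 21.4-fold, the cytochrome P450-like AK099925 16.9-fold and OsPAE1 (AK103487) 12.9-fold lower. A phospholipid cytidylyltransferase (AK068868), of a family that activates head groups for membrane lipids, was at least 62.3-fold lower on Healthy 2. A transposable element transcript (AK066265) was at least 12.2-fold lower there. The named AK065623, AK065423, AK073343 and AK067699 had mean log2 ratios from -5.09 to -3.89, and AK111804, AK100970 and AK101587, dim in NIL22, passed here too.

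**Figure D2:**
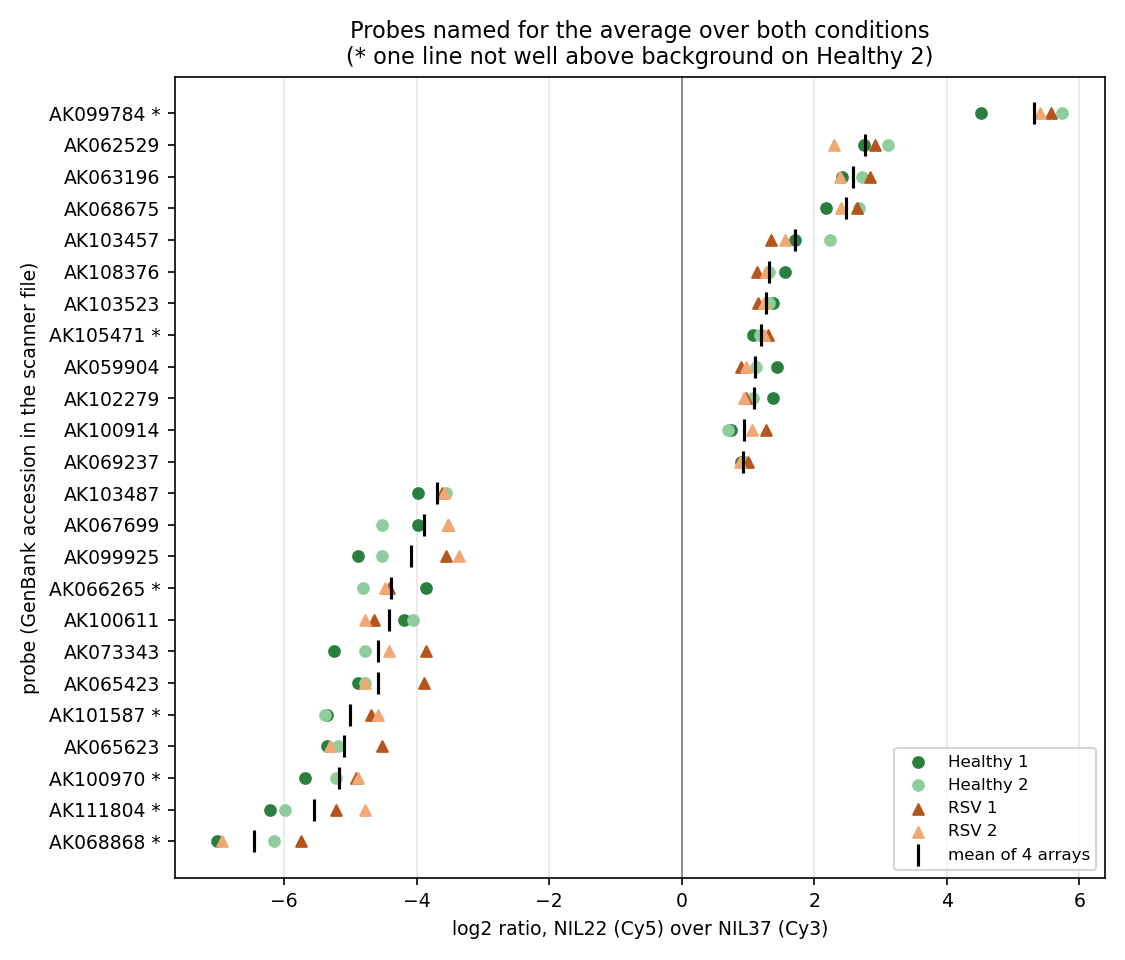
Log2 ratio of NIL22 over NIL37 (horizontal) on each of the 4 arrays for the 24 probes named for the average of both conditions, with a black bar at the mean and an asterisk where a line was not well above background on Healthy 2. All 4 arrays lie on the same side of 0 for each probe, as the naming rule required. The deposited values drawn run from -7.01 for AK068868 on Healthy 1 to 5.75 for AK099784 on Healthy 2. Both probes have an asterisk, and on Healthy 2 only a bound on their fold is known (at least 62.3 and 41.2).

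Of the 122 probes, 113 differed by 2-fold or more, and 47 are described only as unknown expressed proteins. With no test, 32 probes were 2-fold or more higher and 131 were 2-fold or more lower on all 4 arrays. Among the 99 lower probes, 20 were saturated on Healthy 2, 12 of them in both channels. Most of the 16 probes saturated in both channels shared a single ratio on each array, so these 12 calls cannot be read as line differences. Leaving out any of the 4 arrays left 0 probes past the threshold (1639 to 3738 at unadjusted p under 0.05 with limma), and 18 passed with Healthy 2 recomputed by normexp and loess.

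In the list drawn up for NB-LRR proteins, which sense pathogens inside cells, 3 of 117 members were lower and 0 higher in NIL22 on average (5 lower when adjusted over the list alone). A transcript similar to barley MLA13 (AK066312), a powdery mildew resistance protein, was 6.29-fold lower, with a log2 ratio of -2.65 ± 0.11 (SE, adjusted p = 0.0175). On Healthy 2, YR48 (AK069829) was at least 4.53-fold lower and a transcript similar to tomato Ve2 (AK105304) at least 1.60-fold lower. Ve2 is a receptor-like protein of the cell surface and lies outside the NB-LRR class. The list as a whole was not shifted by camera (adjusted p = 0.547). Fry called it (mean -0.14, median -0.02, adjusted p = 0.0432), with 65 members below and 52 above zero. The typical member was thus hardly shifted, and the mean rests largely on the lowest members. Of 286 receptor-like kinases, 2 were higher and 0 lower (2 when adjusted over the list alone), AK099784 and AK105471.

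Other defence lists held no member past the threshold over all probes for the average of both conditions. These were pathogenesis-related proteins (103 probes), phytoalexin synthesis (6), WRKY factors (29), RNA silencing (12) and heat shock proteins (87), with 0 also when adjusted over the list alone. In the jasmonate list (24), the lipoxygenase CM-LOX2 (AK066825) passed as higher when adjusted over the list alone, with a log2 ratio of 0.57 ± 0.06 (SE, adjusted p over all probes = 0.0866). In the salicylate list (28), a salicylic acid methyltransferase (AK070415) did so, at 0.82 ± 0.09 (SE, adjusted p over all probes = 0.0822). In the ethylene list (31), the ACC oxidase AK058296, an enzyme of the last step of ethylene synthesis, did so as lower, at -4.26 ± 0.37 (SE, adjusted p over all probes = 0.0559). Chitinase IIb (AK060363) was at 1.49 ± 0.23 (SE, adjusted p = 0.138). None of these 8 lists was shifted by camera, with adjusted p from 0.134 to 0.995, and fry alone called RNA silencing, with a mean of -0.13 (adjusted p = 0.0432).

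In the list of peroxidases and glutathione S-transferases (134), OsGSTU12 (AK108376) passed as higher and 0 as lower. OsGSTU10 (AK061233) had a log2 ratio of -1.66 ± 0.24 (SE, adjusted p = 0.125). Among 74 proteasome and ubiquitin ligase probes, OsPAE1 was the 1 that passed, and another core subunit, OsPAG1 (AK061784), did not pass, at -0.35 ± 0.07 (SE). In the transposon-related list (55), a Skipper-like retrotransposon transcript (AK060683) was 4.30-fold lower (adjusted p = 0.0375). When adjusted over the list alone, 1 probe was higher and 3 were lower there. Camera gave adjusted p of 0.241 for the first and second of these lists and 0.547 for the third.

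Photosynthesis transcripts could be read only in part, since 16 of the 34 probes of the light harvesting list were saturated. Of these 34 light harvesting and photosystem probes, 6 passed as lower on average (13 when adjusted over the list alone), among them Cab27 (AK060265) and Cab26 (AK060904), and all 6 were saturated on Healthy 2. Camera called the list in healthy leaves (mean log2 ratio -0.50, adjusted p = 7.56e-05), in inoculated leaves (-0.55, adjusted p = 8.64e-07) and on average (-0.52, adjusted p = 2.57e-05). With an estimated correlation the adjusted p was 0.806, 0.700 and 0.760. The 18 unsaturated members had a mean of -0.02 on average, with camera adjusted p = 0.629. In the Calvin cycle list (17), 4 probes for rubisco subunits and rubisco activase passed as lower (5 when adjusted over the list alone), all saturated. The 12 chlorophyll synthesis probes had 0 past the threshold, also when adjusted over the list alone, and camera gave adjusted p = 0.241 and 0.547 for these lists.

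**Figure D3:**
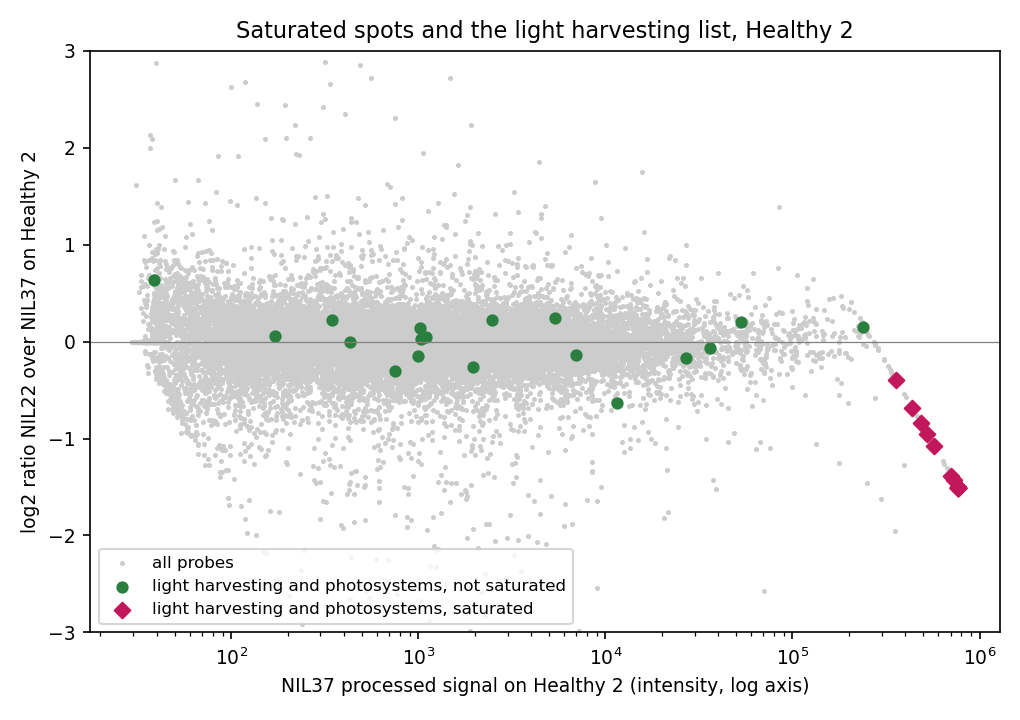
Log2 ratio of NIL22 over NIL37 (vertical, drawn from -3 to 3, which leaves out 54 probes) against NIL37 signal intensity (horizontal, log axis) on Healthy 2, with light harvesting probes as diamonds where saturated and filled circles where not. The 16 saturated members lie between -1.51 and -0.40, and the 18 others between -0.63 and 0.63.

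Ribosomal protein transcripts (169 probes) had a mean log2 ratio of 0.01 in healthy and -0.07 in inoculated leaves, and 117 of 169 shifted towards lower NIL22 signal on inoculation. Camera called the difference of -0.08 between conditions (adjusted p = 0.00451) and the ratio in inoculated leaves (adjusted p = 0.0209). With an estimated correlation the adjusted p was 0.854 and 0.700. In the difference, 0 members passed singly with limma, over all probes or adjusted over the list alone. On average, 1 member passed as lower, a chloroplast S7 transcript (AK060247) saturated in NIL22. The call on the difference was lost without RSV 1 (adjusted p = 0.450), without Healthy 2 (adjusted p = 0.326) and with fry (adjusted p = 0.632). The call in inoculated leaves was lost without RSV 1, without either Healthy array, with a replicate block (adjusted p = 0.0920) and with fry (0.136). It was also lost with saturated probes left out (camera adjusted p = 0.0541). However, 1 of the 169 members was saturated, and the mean was -0.0662 without it against -0.0729. The adjustment over the lists changed too, as the light harvesting list was then no longer called.

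Among the cell type marker lists, in that for epidermis and wax (27) the lipid transfer proteins AK063196 and AK062529 passed as higher on average. When adjusted over the list alone, 3 members were higher and 4 lower, among them the lipid transfer protein LPT IV (AK061288) at -1.31 ± 0.13 (SE, adjusted p over all probes = 0.0739). The list was called by camera in healthy leaves (mean 0.25, adjusted p = 0.0466), with an adjusted p of 0.806 at the estimated correlation, 0.115 without Healthy 1 and 0.146 without Healthy 2. On average its camera adjusted p was 0.0932, and fry called it (adjusted p = 0.0184). Leaving out saturated probes moved the list's camera adjusted p in healthy leaves to 0.0965, though 0 of its 27 members were saturated. In the root and seed list (26), the root-specific RCc2 (AK063090) passed as lower (adjusted p = 0.0460). Its deposited log2 ratios lay between -3.62 and -1.88 on the 4 arrays, but NIL22 was near background on Healthy 2, so the size there is uncertain. In the senescing leaf list (13), the member that passed was SGR2, which lies outside the list's theme, at a log2 ratio of -4.42. Fry called that list (mean -0.37, median -0.02, adjusted p = 0.0432), but its mean rests largely on SGR2. The lists for dividing cells (20), shoot meristem (5) and lignifying cells (35) had 0 members past the threshold, and 1 lower member of the lignifying list, a cinnamoyl-CoA reductase (AK062411, -0.97 ± 0.11, SE), passed when adjusted over the list alone. These 5 lists had camera adjusted p from 0.134 to 0.708 on average.

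Over the 4 comparisons and 23 lists, the mean and median of a list had opposite signs in 9 of 92 cases, and 0 of these were called by camera. No list was called with an estimated correlation, where the smallest adjusted p was 0.700. That test rests on 2 residual degrees of freedom, so it could hardly call any list. In healthy leaves, the epidermis and wax list had an estimated correlation of -0.0358, below the preset 0.01. Its adjusted p by camera still rose from 0.0466 to 0.806. The light harvesting list (0.151) and the ribosomal list (0.0354) had estimated correlations above the preset. Their adjusted p at the preset can therefore be too small.

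Across probes, which are not independent replicates, the Healthy arrays correlated at 0.594 (Pearson) and the RSV arrays at 0.316. Pairs of a Healthy and an RSV array correlated between 0.463 and 0.614, and the condition means at 0.736. Healthy 2, whose title also contains RSV, correlated with RSV 1 (0.598) and RSV 2 (0.614) at least as well as with Healthy 1. Healthy 1 correlated less with RSV 1 (0.463) and RSV 2 (0.474). The difference between the RSV pair and the others was not tested against a spread between plants.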

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

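Apart from the list tests and the test by chromosome, which were planned (the second was not run), the tests in this part were chosen after the results were seen. The ribosomal protein list stood out because camera called the difference of its line ratio between conditions, a shift of -0.0838 (log2) from healthy to inoculated plants. That call was lost with fry (adjusted p = 0.632), without RSV 1 and without Healthy 2. With an estimated correlation the adjusted p by camera was 0.854, but that test, on 2 residual degrees of freedom, called none of the 23 lists. The list's estimated correlation of 0.0354 lay above the preset 0.01, so its p at the preset can be too small. The positive control spots of the scanner grid, which no comparison uses, had a median log2 ratio of -3.82 on RSV 1 against -5.48, -5.48 and -5.55 on Healthy 1, Healthy 2 and RSV 2. Another set of control spots, 362 per array, had medians of -3.39 on RSV 1 against -6.05, -6.25 and -6.61. Both sets had the same direction on all 4 arrays. At 2-fold or more, 239 probes were higher and 456 lower on Healthy 1, 128 and 327 on Healthy 2, 122 and 658 on RSV 1, and 407 and 329 on RSV 2, the only array with more higher than lower.

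More probes were lower than higher in NIL22 across both conditions, 81.1% of the 122 (95% exact binomial interval 73.1 to 87.7). Among probes well above background in both channels on the 1 array with spot flags, 76.6% of those called were lower (70.4 to 82.1). This argues against surrogate values on that array as the whole cause. Among probes without saturation or outlier flags there it was 79.5% (68.8 to 87.8), which argues against saturation on that array as the whole cause. Surrogate values and saturation on the other 3 arrays stay open, as their flags are not known. Of the 16 probes saturated in both channels on Healthy 2, 10 shared a single ratio on Healthy 1, 12 on RSV 1 and 14 on RSV 2. All these intervals treat probes as independent, though the called probes come from the same 4 arrays. A dye effect specific to genes and true differences between the lines cannot be told apart, since 0 arrays had the dyes swapped. Donor segments that differ between the lines may also play a part, but 0 probes could be placed on a chromosome. Sequence differences between the lines under the probes were not examined and stay open too.

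The RSV arrays correlated less with each other (0.316 across probes) than any other pair, including pairs from different conditions. Removing trends over the slide and with the Healthy 2 intensity left 0.321, below the lowest correlation between conditions of 0.470, and moved no correlation by more than 0.00766, which argues against these trends, while a trend with the RSV arrays' own intensity stays open, as intensities were there for 0 of them. The partial correlation of the RSV arrays was -0.0809 given Healthy 2 (95% bootstrap interval over probes -0.102 to -0.0596) and 0.123 given Healthy 1 (0.0960 to 0.150), and since one shared signal with independent noise needs both at 0 or above, the first argues against independent noise as the whole cause, though the intervals treat probes as independent. A label swapped between conditions stays open, because in 0 of the 3 ways to pair the arrays, the labelled way included, did both pairs correlate above all pairs across them. A difference between the inoculated plants, or in the handling of RSV 1, whose control spots (-3.82 and -3.39) stood apart, also stays open and was not tested, as no label separates them.

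The light harvesting list was lower in NIL22 on all 4 arrays, with a mean of -0.523 on average. Its 18 unsaturated members had a mean of -0.0155 (SE 0.0478 over these probes, which are not independent replicates). Saturation as the source of the shift would give such a mean. Of the 16 probes saturated in both channels on Healthy 2, 9 of them in this list, the commonest ratio was shared by 10 on Healthy 1, 14 on Healthy 2, 12 on RSV 1 and 14 on RSV 2. The mean of the unsaturated members argues against lower photosynthetic transcripts in NIL22 as a class. Whether the 16 saturated members differ stays open, since the ceiling sets both signals of 9 of them, and for the 7 saturated in NIL22 alone the ratio on Healthy 2 is a lower bound.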

How the results depend on the processing

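Trend removal and leaving out saturated probes were chosen after seeing the data. Counts are given with higher and lower probes in brackets, and the cause of a shift was not tested unless given. In healthy plants, 23 probes became 41 (5, 36) with centring, 48 (7, 41) with scaling, 37 (6, 31) with quantiles, 52 (9, 43) with loess, 54 (9, 45) with trends removed, 46 (10, 36) and 62 (12, 50) with probes above background in both or at least 1 channel, 51 (9, 42) with a trended robust prior, 6 (0, 6) with normexp, 264 (58, 206) at 2-fold on every array, and 0 with its own arrays only (2523 at unadjusted p under 0.05). In inoculated plants, 14 became 24 (0, 24), 26 (4, 22) with quantiles, 36 (6, 30), 35 (6, 29), 29 (6, 23) and 44 (9, 35), 32 (5, 27), 5 (0, 5), 222 (50, 172) and 0 (1205 unadjusted) in that order without scaling, and 0 with a replicate block (1655 unadjusted). On average, 122 became 79 (14, 65) with quantiles, 199 (44, 155) with loess, 201 (46, 155) with trends removed, 218 (51, 167) and 252 (56, 196) above background, 78 (16, 62) without spot flags and 18 (3, 15) with normexp. For the difference, 11 probes (7, 4) shifted 2-fold with no test, and every other setting run gave 0 with limma (194 to 1547 at unadjusted p under 0.05 without each array). Without each array in turn, these 4 counts ranged from 0 to 0, with 1 residual degree of freedom and the lone array assumed to vary like the other group. As deposited, 85 probes had no spread at all, against 0 after centring or the filter on both channels, where the prior degrees of freedom were 2.08 and 2.54 against 1.91. Centring and loess kept all 23 healthy, 14 inoculated and 122 average calls. Of the 122, 64 were kept with quantiles, 15 with normexp, 103 and 122 above background, 78 without spot flags, 102 with the trended robust prior and 73 with a replicate block. The block kept 13 of 23 healthy calls, and scaling 12 of 14 inoculated calls.

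Lists called in healthy plants went from 2 to 1 with quantiles or trends removed and to 0 without saturated probes or with an estimated correlation (leave-one-out 1 to 2). In inoculated plants 2 became 0 without saturated probes, with an estimated correlation or with fry, and 1 with a replicate block (leave-one-out 1 to 5). For the difference, 1 became 0 with an estimated correlation or fry (leave-one-out 0 to 3). On average, 1 became 2 with either background filter, 0 without saturated probes or with an estimated correlation, and 4 with fry, which tests a list on its own and not against other probes (leave-one-out 1 to 1). Spearman correlations were lower than Pearson ones, at 0.373 for the Healthy pair, 0.0507 for the RSV pair, 0.274, 0.289, 0.436 and 0.400 for Healthy 1 with RSV 1 and RSV 2 and Healthy 2 with RSV 1 and RSV 2, and 0.527 for the condition means. The other 103 values stayed within 1.5 times the main count or the spread of the correlations. Some of them could not move. The mean over the probes of a gene changed nothing, as each accession had 1 probe, and the scanner log ratio equalled the deposited Healthy 2 values. Others are counts for the difference that were 0 and stayed 0. For named genes, 0 directions reversed under any setting run. The naming rule took probes with the same direction on every array, so this outcome was largely fixed in advance. Those named on average stayed on their side of the threshold in 266 cases and fell short in 134, all without each array in turn or with quantiles, normexp, a replicate block or no spot flags. Chromosome alternatives were not run. Flags for 1 array limit what is known of signal over background on the other 3.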

Other observations

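The tests in this part were chosen after the data were seen. Probes described only as unknown expressed proteins made up 38.5% of the 122 probes that passed on average and 25.8% of the rest (two-sided Fisher's exact test over probes, p = 0.00246, odds ratio 1.80). That p treats probes as independent, though all calls come from the same 4 arrays, and signal level was not taken into account. Probes at 8-fold or more on all 4 arrays were 25 lower, of which 11 were dim in NIL22 on Healthy 2, and 3 higher, of which 2 were dim in NIL37. The 79 unsaturated probes that passed as lower on average had a median log2 ratio of -2.37 in healthy and -1.91 in inoculated plants, and 63 of them were nearer to 0 in inoculated plants. Their medians on the single arrays were -2.53 and -2.48 for Healthy and -1.98 and -1.88 for RSV. The 23 higher probes had medians of 1.55 in healthy and 1.30 in inoculated plants, and 11 were nearer to 0 in inoculated plants. These differences between conditions were not tested as a set.

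The scanner software's own model for Healthy 2 alone gave 446 probes higher and 689 lower in NIL22 at a p under 0.01. These p-values describe a single array and no replicate error.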
